A study of Homo sapiens with 6 samples.

How the data were processed

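The data are RNA sequencing counts from 6 libraries of H69AR cells, 3 with a control shRNA and 3 with a DDX5 shRNA, assigned to groups by the lentivirus named in the labels. Per the labels' protocols, RNA was treated with DNase and made into stranded total RNA libraries after ribosomal RNA depletion. The submitters' processing notes name Trim Galore 0.4.4, STAR 2.5.4b, HTSeq and the build GRCh38. The annotation release, the strand setting and the treatment of reads shared between genes are not given in the sources used here. The authors deposited 1 table of raw counts per Ensembl gene, whole numbers without normalization, with 58395 genes and totals of 68124247 to 95225903 counts per library. All its columns were used, and 20416 genes had no count in any library. Symbols came from a gene name table (57754 identifiers matched) and positions, classes, lengths and 3′ UTRs from GENCODE 29 on GRCh38 (58275 matched), which may differ from the annotation the authors counted on.

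Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes passed edgeR's expression filter with its default settings, leaving 20356, and were scaled by TMM. A quasi-likelihood model with group as its term and robust dispersion estimates gave two-sided p-values, adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was the fold change divided by the square root of its F statistic. The biological coefficient of variation was 0.166. CPM values are TMM-scaled, and fold changes are DDX5 shRNA over control shRNA. The 1 tested gene without counts in any control library and the 4 without counts in any DDX5 shRNA library were also set at the bound that 3 counts over the group allow. Counting intervals are not given for single values, since the spread between libraries was larger: every pair of libraries within a group differed by more than sampling noise (chi-square per gene at least 13.7), so none was counted as a duplicate.

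Before the data were examined, 45 gene lists with 1190 entries were fixed: subunits of OXPHOS complexes I to V, mitochondrially encoded mRNAs and rRNAs, OXPHOS assembly factors, mitochondrial ribosomal proteins, synthetases, biogenesis and import, metabolic pathways, stress and signalling targets, cell cycle, histones, ribosome, RNA processing, tumour and drug resistance markers, extracellular matrix, and other cell types. The nuclear OXPHOS list is the union of the 5 complexes. Lists with at least 3 tested members, 44 with the union, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over those lists. No camera call held with an estimated correlation. The directional and mixed tests of fry ask whether a list's own genes move one way or in either direction, and compare it with no other genes. "Rose" and "fell" mean called in the edgeR fit. A count adjusted over the list alone uses Benjamini-Hochberg within the list. Gene classes were tested with Fisher's exact test.

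The rule for named genes was fixed together with the lists. DDX5 and DDX17 are always named, then the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between the groups, without pseudogenes and clone-type names. Each list gives up to 4 members with the smallest edgeR p, or 2 by value where none is called. Some genes that the rule picked are not reported here. Overlapping genes are named because they overlap, whatever their values. Not every overlap is named, and other list members that overlap a gene are uncertain to the same extent.

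The shRNA sequence was searched exactly, in both orientations, in 206694 GENCODE 29 transcripts. Seed sites were 7-base matches to positions 2 to 8 of the guide, or of the opposite strand, in the longest 3′ UTR of protein-coding transcripts. The guide was taken to be the printed sequence from its first base, and seeds of a guide cut elsewhere were not tested. The groups of genes with and without a site were compared by their median log2 fold change, ranked among other 7-mers of equal GC content and a similar number of genes. Length and GC content were tested with 10000 random lists, each member drawn from its 200 nearest protein-coding genes in that property and mean expression. Along the chromosomes, windows of 50 tested genes in steps of 10 were compared with 1000 shuffles of the gene order. For the stretches, a trend with GC content, length and mean expression (natural splines with 5 degrees of freedom) was first taken out. The neighbour and window tests were first run in a narrower form than the one written down for them, then recoded as written. In the narrower form, 165 protein-coding neighbours outside the group had a median of -0.20 (95% bootstrap interval -0.42 to -0.12), and 103 of 1016 windows of protein-coding genes lay beyond every shuffle. The text uses the forms written down and gives the narrower neighbour value beside them.

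Alternatives were RLE, upper-quartile and no scaling, no filter and a filter of at least 50 counts in 3 libraries, mitochondrially encoded genes left out, DESeq2 1.42.0, limma voom, the replicate number as a block, each library left out in turn, a test against a fold of 1.5, a threshold of 0.01, protein-coding genes alone, and the other set tests. After the data were seen, 2 were added: trends of length and GC content per library taken out as offsets, and genes in the shifted stretches left out. The workflow was tested on simulated counts for this comparison, with 200 changed genes among 19774 tested. It recovered 35.7% of genes changed 1.5-fold, 81.0% of those changed 2-fold and 100% of those changed 4-fold, and 9.49% of its 158 calls were unchanged genes. A lowered list of 60 genes was called by camera with preset and with estimated correlation. The simulated genes were drawn independently of each other. The simulation therefore does not test lists whose genes vary together, such as the nuclear OXPHOS list (estimated correlation 0.462). Genes of the Y chromosome and the genes that mark X inactivation are not reported.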

Results

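RNA levels were measured by sequencing ribosomal-RNA-depleted, strand-marking total RNA libraries from H69AR cells, a small cell lung cancer line selected for resistance to doxorubicin. The cells carried a lentiviral shRNA that doxycycline switches on, either a control shRNA or 1 shRNA against DDX5, and were given 1 µg/ml doxycycline for 3 days. Each group had 3 libraries. Control replicates 1 to 3 held 77218383, 68124247 and 95225903 counts, and DDX5 shRNA replicates 1 to 3 held 73801561, 78012378 and 72399246. The study's title names mitochondrial function, so the comparison asks which genes, and among them which mitochondrial gene groups, differ once DDX5, an RNA helicase of the DEAD-box family, is depleted. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. With 1 shRNA, effects of DDX5 loss and other effects of that shRNA were not separated.

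DDX5 was lower in all 3 DDX5 shRNA libraries. DDX5 (ENSG00000108654, GRCh38 chromosome 17, 64499616 to 64508199, minus strand) fell by 2.15 on the log2 scale (SE 0.0693, n = 3 per group, edgeR adjusted p = 1.81e-06), a 4.45-fold fall. Its level was 537 ± 18.02 CPM (counts scaled by library size, mean ± SD) in the control libraries and 121 ± 2.32 CPM in the DDX5 shRNA libraries. The close paralog DDX17 (ENSG00000100201, chromosome 22, 38483440 to 38507660) rose by 0.54 (SE 0.0723, edgeR adjusted p = 0.000961), from 359 ± 7.13 to 522 ± 29.1 CPM. The shRNA sequence, ATCCAATCCACTTAGAGCA, is antisense to its target. Its reverse complement, TGCTCTAAGTGGATTGGAT, matched 12 transcripts of DDX5 exactly and those of no other gene, among 206694 annotated transcripts searched. The match lies at 64504025 to 64504043 on chromosome 17, in the coding sequence, in exon 4 of the transcript ENST00000225792.9. DDX5 overlaps CEP95 and DDX17 overlaps KDELR3, each on the opposite strand. The strand setting of the counting is not given in the sources used here, so reads of overlapping genes could be shared. CEP95 differed by -0.02 (edgeR adjusted p = 0.855), and KDELR3 fell by 1.45 (edgeR adjusted p = 0.000337), from 5.46 to 2.001 CPM.

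**Figure D1:**
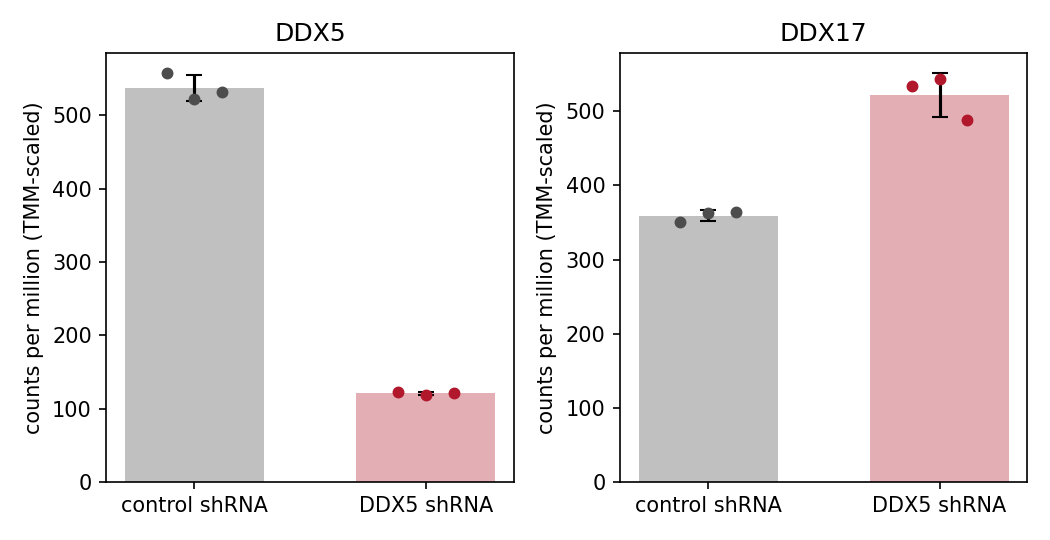
DDX5 and DDX17 in TMM-scaled CPM, on a linear axis from 0. Points are the 3 libraries per group, bars the group mean and error bars the SD; DDX5 was 537 CPM in the control and 121 CPM in the DDX5 shRNA libraries, and DDX17 359 and 522 CPM.

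The transcriptome differed widely between the groups. Of 20356 genes tested, 8784 changed, 4365 of them higher and 4419 lower in the DDX5 shRNA libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p threshold 0.05). At least 2-fold changes were called for 3047 genes, 1228 higher and 1819 lower, and these counts were the same with the 5 changed genes that had no count in 1 group set at their bound. The groups did not overlap for 56.8% of the genes tested, against 10% by chance for 3 libraries against 3. Without control replicate 1 the count of changed genes was 5550, 2764 higher and 2786 lower. It was 5003 at an adjusted p threshold of 0.01, and 2199 in a test against a 1.5-fold change.

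Among the genes with the largest rises was F2RL2 (ENSG00000164220, chromosome 5, 76615482 to 76623434), which encodes a protease-activated receptor. It rose by 6.08 (SE 0.175, n = 3 per group, edgeR adjusted p = 1.15e-06), from 0.283 ± 0.0644 to 19.1 ± 1.59 CPM. PRICKLE2, a planar cell polarity gene, rose by 3.95 (SE 0.0920). CCN2, which encodes connective tissue growth factor, rose by 3.13 (SE 0.0938), from 4.77 ± 0.159 to 41.8 ± 2.33 CPM, and COL6A2, a collagen VI chain, by 2.97 (SE 0.208). The rest of the 10 largest rises were OSBP2 (3.43), IGFN1 (3.35), TMPRSS15 (3.13), EPPK1 (3.09), ZNF423 (3.03) and RAPGEF4 (2.88). Their edgeR adjusted p ranged from 4.55e-06 (RAPGEF4) to 0.000130 (EPPK1).

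SLFN11 (ENSG00000172716, chromosome 17, 35350305 to 35373701), which sensitises cells to DNA-damaging drugs, fell by 6.51 (SE 0.142, n = 3 per group, edgeR adjusted p = 4.61e-07). Its level was 24.8 ± 0.811 CPM in the control and 0.270 ± 0.0431 CPM in the DDX5 shRNA libraries. ADGRB3, an adhesion receptor of neurons, fell by 5.88 (SE 0.364), from 142 ± 12.01 to 2.42 ± 1.39 CPM. GUCY1A2, a subunit of the nitric oxide receptor guanylate cyclase, fell by 5.88 (SE 0.531), and SLC8A1, a sodium-calcium exchanger, by 5.47 (SE 0.336). KIAA1217 (-5.21), CUX2 (-5.15), NECTIN3 (-5.12), LINC02154 (-5.08), KCNT2 (-5.08) and FEZ1 (-4.94) completed the 10 largest falls. FEZ1 lies in a stretch of chromosome 11 in which most genes were lower, described with the chromosome values. Several of these genes overlap a gene on the opposite strand, and their values are uncertain to that extent. NECTIN3 overlaps the more abundant NECTIN3-AS1, which fell by 4.51, and FEZ1 overlaps STT3A (-0.69) and EI24 (-1.17). PRICKLE2 overlaps PRICKLE2-AS1 (6.69), and F2RL2, CCN2, RAPGEF4, GUCY1A2 and SLC8A1 overlap less abundant genes.

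Nuclear genes for subunits of the oxidative phosphorylation (OXPHOS) complexes were mostly lower. Of 68 tested, 46 fell and 1 rose (49 and 2 adjusted over the list alone), with a median log2 fold change of -0.56 (camera adjusted p = 9.67e-08). With an estimated correlation between genes the adjusted p = 0.577. The complex I subunit NDUFA1 fell by 1.27 (SE 0.118, edgeR adjusted p = 0.000176), the ATP synthase subunit ATP5MG by 1.27 (SE 0.129), the complex IV subunit COX7C by 1.19 (SE 0.127) and the complex III subunit UQCRH by 0.95 (SE 0.116). NDUFA1 and ATP5MG lie in stretches of chromosomes X and 11 in which most genes were lower. In complex I, 19 of 31 subunits fell (21 fell and 1 rose adjusted over the list alone), with a median of -0.33 (camera adjusted p = 0.000612). Complex IV had 8 of 10 lower (median -0.77, camera adjusted p = 0.00273) and complex V 12 of 16, or 13 adjusted over the list alone (median -0.60, camera adjusted p = 0.000540). These 3 lists had an adjusted p = 0.577 with an estimated correlation. With trends of length and GC content taken out, a setting chosen after the data were seen, their medians were -0.18, -0.37 and -0.38 and that of all 68 genes -0.27, all called. Complex III had 5 lower and 1 higher of 8 (median -0.53, camera adjusted p = 0.0642; adjusted p = 0.577 with an estimated correlation). It was called without control replicate 3 (0.0465) or DDX5 shRNA replicate 2 (0.0370), without a low-count filter (0.00798) and with genes in the shifted chromosome stretches left out (0.0125). Complex II had 2 lower of 3, SDHB (-0.55) and SDHA (-0.23) (median -0.23, camera adjusted p = 0.427). The SDHA call was lost without any one of the libraries except DDX5 shRNA replicate 3, and without a low-count filter. Short transcripts as a class were lower in the DDX5 shRNA libraries. For the 2782 shortest and the 2782 longest protein-coding transcripts, the median deviation of the short minus that of the long ones was 0.20, 0.11 and 0.09 (log2) in control replicates 1 to 3, and -0.24, -0.08 and -0.05 in DDX5 shRNA replicates 1 to 3. Some short RNA classes differed the same way. Miscellaneous RNA took 0.537%, 0.318% and 0.385% of the counts of control replicates 1 to 3. In DDX5 shRNA replicates 1 to 3 it took 0.158%, 0.133% and 0.182%. Small nucleolar RNA took 0.0339%, 0.0203% and 0.0229% against 0.0111%, 0.00973% and 0.0114%. Small nuclear RNA overlapped between the groups, at 0.0419%, 0.00950% and 0.0167% against 0.0127%, 0.00992% and 0.0107%. Of 25 microRNA genes tested, 5 were higher and 1 lower (median log2 fold change 0.37). The median OXPHOS transcript is 1090 bases long, against 3145 for tested protein-coding genes.

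The mRNAs encoded in the mitochondrial genome gave a single call in the main fit. Of 13 tested, 1 fell, MT-CO2 (-0.59, SE 0.192, edgeR adjusted p = 0.0396), and none passed adjusted over the list alone (median 0.18, camera adjusted p = 0.761). The list median turned on single libraries: it was 0.56 without control replicate 1, 0.30 without DDX5 shRNA replicate 1, 0.11 without DDX5 shRNA replicate 2, -0.12 without control replicate 2 and -0.04 without DDX5 shRNA replicate 3. With the trends of length and GC content taken out, a setting chosen after the data were seen, it was 0.59, and none of these settings gave a camera call. The MT-CO2 call was lost without any one of control replicates 1 and 3 and DDX5 shRNA replicates 1 and 2, without the low-count filter (adjusted p = 0.147), and with the trends out (-0.15, adjusted p = 0.677). MT-ND2 differed by 0.66 (edgeR adjusted p = 0.0611). It was called by DESeq2 (adjusted p = 0.0145) and, at 0.898, without DDX5 shRNA replicate 1 (adjusted p = 0.0139), and was at 0.43 without DDX5 shRNA replicate 3 and 1.17 with the trends out, uncalled in both. MT-CO3 was at -0.42 (edgeR adjusted p = 0.0996); it was called at -0.56 without control replicate 2 (adjusted p = 0.0476) and was at -0.23 without control replicate 1 and -0.016 with the trends out, uncalled. The mitochondrial rRNAs MT-RNR1 (0.69, SE 0.913, edgeR adjusted p = 0.568) and MT-RNR2 (0.10, SE 0.628, edgeR adjusted p = 0.914) varied between libraries. With 1 library left out MT-RNR1 ran from 0.18 to 2.38, called at 2.38 without control replicate 1, and MT-RNR2 from -0.33 to 1.19, uncalled. Mitochondrial rRNA made up 0.249% of the counts of control replicate 1 and between 0.0345% and 0.194% of those of the other libraries, all made after depletion of ribosomal RNA.

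Genes of the mitochondrial translation machinery split. Of 71 mitochondrial ribosomal proteins 38 fell and none rose, also adjusted over the list alone (median -0.28, camera adjusted p = 8.62e-05), among them MRPL35 (-1.22) and MRPL33 (-1.02). Of 15 mitochondrial aminoacyl-tRNA synthetases, which charge the tRNAs used in mitochondria, 8 rose and none fell, also adjusted over the list alone (median 0.29, camera adjusted p = 0.0368). Among them were FARS2 (0.73) and LARS2 (0.56). Of 45 OXPHOS assembly factors 19 fell and 5 rose (20 and 5 adjusted over the list alone; median -0.24, camera adjusted p = 0.0368). FOXRED1 fell by 0.98 and LYRM7 by 0.67, and UQCC1 rose by 0.59, FOXRED1 and UQCC1 lying in shifted stretches of chromosomes 11 and 20. FOXRED1 overlaps the more abundant SRPRA (-0.33) and LYRM7 the more abundant HINT1 (-0.84), each on the opposite strand. Their values are uncertain to that extent. These 3 lists had an adjusted p = 0.577 with an estimated correlation. The assembly factor call was lost without control replicate 1 (0.0539), control replicate 2 (0.0598) or DDX5 shRNA replicate 1 (0.102). The synthetase call was lost without control replicate 1 (0.0560), control replicate 3 (0.0573) or DDX5 shRNA replicate 2 (0.0612). With the trends of length and GC content taken out, both were lost (0.313 and 0.0575), and the median of the mitochondrial ribosomal proteins was -0.10, still called.

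Metabolic lists had members on both sides and no camera call. Of 21 genes of the TCA cycle, the mitochondrial pathway that oxidises acetyl groups, 8 fell and 2 rose (9 and 2 adjusted over the list alone; median -0.23, camera adjusted p = 0.258). The rising members were PC (1.89), pyruvate carboxylase, and PDHA1 (0.42), a subunit of pyruvate dehydrogenase, and SDHB (-0.55) and IDH3A (-0.52) were among the falling ones. Of 19 glycolysis genes 4 rose and 4 fell (4 and 3 adjusted over the list alone; median 0.05, camera adjusted p = 0.512). The rises were the glucose transporters SLC2A3 (2.47) and SLC2A1 (0.61) and the enzymes HK2 (0.89) and GPI (0.90), GPI lying in a shifted stretch of chromosome 19. In mitochondrial fatty acid oxidation 8 of 18 fell and 3 rose (median -0.08, camera adjusted p = 0.308), with ACADL at -2.16 and HADHB, in the shifted stretch of chromosome 2, at -0.62. ACADL was scarce, at a mean log2 CPM of -0.65, and overlaps the similarly scarce AC006994.2 on the opposite strand. HADHB overlaps the more abundant HADHA (-0.48) on the opposite strand. In serine and one-carbon metabolism 6 of 16 fell and 2 rose (median -0.13, camera adjusted p = 0.277), with ALDH1L1 at -4.11 and MTHFD1L at 0.57. Coenzyme Q biosynthesis had 2 rising and 2 falling of 13, such as COQ6 (-0.49) (median -0.12, camera adjusted p = 0.454). Mitochondrial protein import had 8 falling and 2 rising of 28 (median -0.16, camera adjusted p = 0.299), with TOMM7 at -0.95 and PAM16 at 1.45. PAM16 had a mean log2 CPM of only 1.14. It overlaps the more abundant GLIS2 on the opposite strand and CORO7 on the same strand, so its value is uncertain. Factors of mitochondrial DNA maintenance, transcription and biogenesis had 4 falling and 2 rising of 21, or 3 and 2 adjusted over the list alone (median -0.12, camera adjusted p = 0.643). NRF1, a transcription factor for nuclear genes of mitochondrial proteins, rose by 0.37. The calls of PRIMPOL (-0.32), MTERF3 (-0.37) and MGME1 (-0.24) in that list were each lost without 1 of several libraries. With length and GC trends taken out none of them was called, at 0.0022, 0.083 and -0.038. Cholesterol biosynthesis had 8 falling and 3 rising of 24 (median 0.07, camera adjusted p = 0.696), with HMGCS1 at -0.65. The list-alone counts equalled these where none is given.

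**Figure D2:**
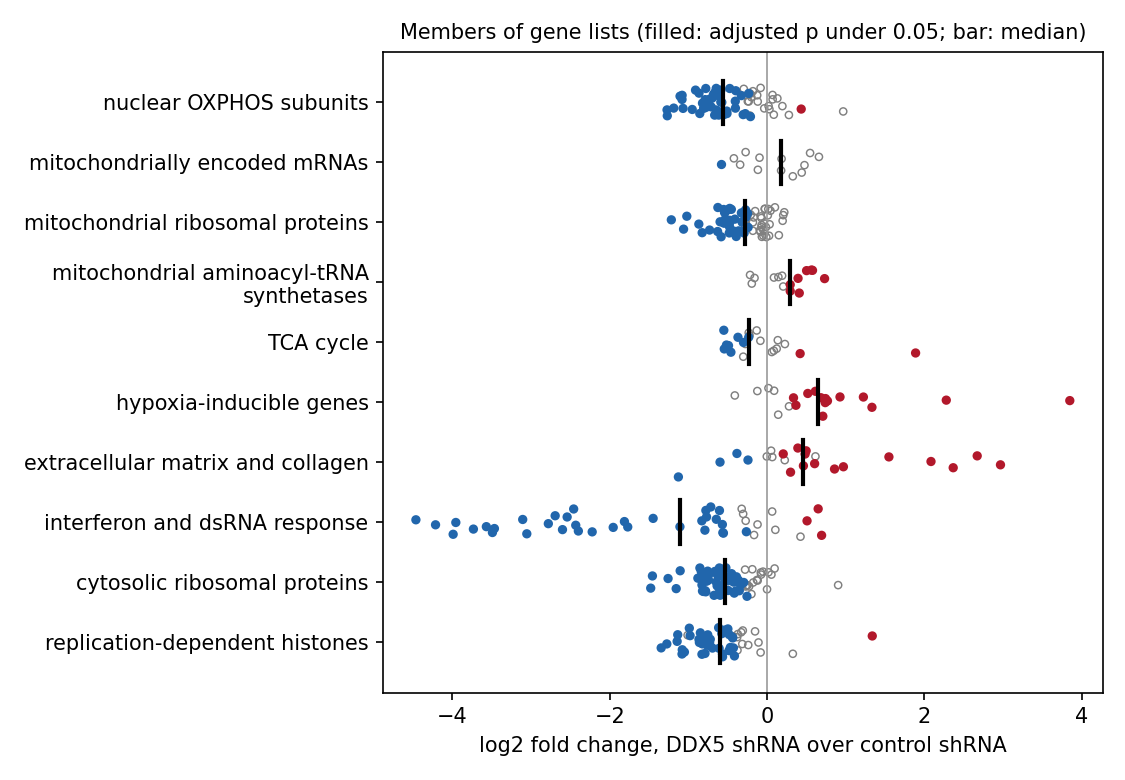
Log2 fold changes (DDX5 shRNA over control shRNA) of the members of 10 gene lists. Each point is a gene, filled where edgeR called it (blue lower, red higher), and the bar is the list median: -0.56 for nuclear OXPHOS subunits, 0.18 for mitochondrially encoded mRNAs, -1.11 for the interferon list and 0.65 for the hypoxia list.

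Interferon-stimulated and double-stranded RNA response genes fell furthest among the lists that camera called. Of 45 tested, 34 fell and 3 rose (36 and 3 adjusted over the list alone), with a median of -1.11 (camera adjusted p = 2.24e-11; adjusted p = 0.476 with an estimated correlation). IFIH1, which encodes the double-stranded RNA sensor MDA5, fell by 3.96 (SE 0.159, edgeR adjusted p = 4.47e-06), OAS1 by 3.57, RSAD2 by 3.73 and HERC5 by 4.46. Hypoxia-inducible genes rose, 14 of 20 with none lower, also adjusted over the list alone (median 0.65, camera adjusted p = 8.62e-05; adjusted p = 0.577 with an estimated correlation). NDRG1 rose by 3.85 (SE 0.169, edgeR adjusted p = 5.96e-06), the carbonic anhydrase CA9 by 2.28, the collagen prolyl hydroxylase P4HA2 by 1.23 and EGLN3, which hydroxylates HIF, by 1.33. Of 23 extracellular matrix and collagen genes 14 rose and 4 fell, also adjusted over the list alone (median 0.46, camera adjusted p = 0.00706; adjusted p = 0.577 with an estimated correlation). FN1, fibronectin, rose by 1.55, COL5A1 by 2.67 and LAMC1 by 0.86. With the trends of length and GC content taken out, the call of the matrix list was lost (0.0752, median 0.29); its median transcript is 5543 bases long.

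Genes of the cytosolic ribosome and the histones fell. Of 74 cytosolic ribosomal proteins 55 fell and none rose (59 and none adjusted over the list alone; median -0.53, camera adjusted p = 5.46e-10), with RPS25 at -1.46, RPL39 at -1.48, RPS7 at -1.10 and RPL37 at -1.15. RPS25, RPL39 and RPL37 lie in shifted stretches of chromosomes 11, X and 5. Many ribosomal protein genes have processed pseudogene copies, and how shared reads were counted is not given in the sources used here. Of 52 replication-dependent histones 37 fell and 1 rose (41 and 1 adjusted over the list alone; median -0.59, camera adjusted p = 2.51e-08), among them H1-4 (-0.83) and H2BC8 (-1.08). Histone genes are near-identical copies, so single values are uncertain. Of 17 small nucleolar RNA host genes 11 fell and 1 rose (13 and 1 adjusted over the list alone; median -0.47, camera adjusted p = 0.00341), with SNHG6 at -0.996 and SNHG29 at -0.79. Their mean, -0.22, lay nearer 0. These 3 lists had an adjusted p = 0.577 with an estimated correlation. The differences between the groups in short transcripts, miscellaneous RNA and small nucleolar RNA stand beside them. Median lengths were 1056 bases for the ribosomal proteins and 529 for the histones. With length and GC trends out the medians were -0.33 for the ribosomal proteins and -0.28 for the small nucleolar RNA host genes, both called. Ribosome biogenesis factors went both ways, 10 lower and 9 higher of 48, or 10 and 8 adjusted over the list alone (median -0.07, camera adjusted p = 0.533), with BRIX1, in the shifted stretch of chromosome 5, at -1.35 and LTV1 at 0.60.

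Cell cycle genes were modestly lower. Of 55 genes of the G2 and M phases 19 fell and 2 rose (18 and 2 adjusted over the list alone; median -0.23, camera adjusted p = 0.0126), among them CCNB1 (-0.78), cyclin B1, and HMMR (-1.15). Of 44 S phase genes 18 fell and 5 rose (19 and 5 adjusted over the list alone; median -0.18, camera adjusted p = 0.0368), with RRM2, a ribonucleotide reductase subunit, at -1.07 and CCNE2 at -0.98. RRM2 had a mean log2 CPM of only 1.14 and overlaps the more abundant AC007240.1 (0.29, edgeR adjusted p = 0.184) on the same strand. Its value is uncertain to that extent. Both lists had an adjusted p = 0.577 with an estimated correlation. The S phase call was lost without control replicate 1 (0.0560), control replicate 2 (0.0711) or DDX5 shRNA replicate 3 (0.0568), and with the trends of length and GC content taken out (0.151). The G2 and M phase median was -0.13 with these trends out and -0.12 without DDX5 shRNA replicate 3, called in both. Of 27 p53 target genes 9 fell and 2 rose (median -0.22, camera adjusted p = 0.0668), with the cell cycle inhibitor CDKN1A at -1.31 and BTG2 at -1.12. Apoptosis regulators had 8 falling and 5 rising of 25, or 11 and 5 adjusted over the list alone (median -0.23, camera adjusted p = 0.258), with BIRC3 at -1.29 and BCL2L11 at 0.66. MYC target genes had 8 falling and 3 rising of 23 (median -0.07, camera adjusted p = 0.533), with ODC1 at -0.51 and TERT at 1.85.

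Lists tied to known roles of DDX5 in RNA processing and transcription gave no camera call in the main fit. DEAD-box helicases had 7 falling and 4 rising of 29 (median -0.02, camera adjusted p = 0.512), with DDX27, in a shifted stretch of chromosome 20, at 0.58 and DDX1 at -0.68. MicroRNA processing genes had 8 rising and 3 falling of 14, or 9 and 3 adjusted over the list alone (median 0.37, camera adjusted p = 0.162), with DROSHA at -0.54, in the shifted stretch of chromosome 5, and XPO5 at 0.40. Splicing genes had 10 rising and 8 falling of 49, or 8 and 7 adjusted over the list alone (median 0.02, camera adjusted p = 0.854), with PRPF6 at 0.68 and SNRPD3 at -0.50. Steroid receptor coregulators and other transcriptional partners of DDX5 had 7 rising and 2 falling of 13 (median 0.30, camera adjusted p = 0.162), with RUNX2 at 1.08 and CREBBP at 1.02. Beta-catenin target genes had 5 rising and 5 falling of 16, or 6 and 5 adjusted over the list alone (median 0.10, camera adjusted p = 0.676), with LGR5 at 2.33, RNF43 at -3.87 and CCND1, cyclin D1, at -1.43. RNF43 overlaps the more abundant SUPT4H1 (-0.55) on the same strand, so its value is uncertain. NF-kB target genes had 6 falling and 3 rising of 16 (median 0.07, camera adjusted p = 0.475), with the chemokine CCL2 at -4.62 and IL1B at -3.91. Their median turned to -0.13 without DDX5 shRNA replicate 3, uncalled, and with the trends of length and GC content taken out it turned to -0.22 and the list was called (0.0402; adjusted p = 0.702 with an estimated correlation in the main fit).

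Markers of tumour state, drug response and stress also had members on both sides. Of 13 neuroendocrine small cell lung cancer markers 6 fell and 4 rose (median -0.39, camera adjusted p = 0.278), with NCAM1 at -4.07, in the shifted stretch of chromosome 11, and POU3F2 at -2.46. Of 27 non-neuroendocrine and mesenchymal markers 8 rose and 8 fell (median 0.12, camera adjusted p = 0.587), with SNAI1, in a shifted stretch of chromosome 20, at 1.82 and NOTCH2 at 0.56. Of 20 drug efflux and drug resistance genes 9 fell and 4 rose (median 0.08, camera adjusted p = 0.366), with ABCC6 at -2.09, ALDH3A1 at -2.24 and ABCB4 at -4.51 beside SLFN11. NRF2 target genes had 6 falling and 1 rising of 16 (median -0.36, camera adjusted p = 0.0594), with NQO1 at -0.89 and HMOX1 at 1.03. The list was called without DDX5 shRNA replicate 1 (0.0398) or 3 (0.0426), by camera on ranks (0.0483), without a low-count filter (0.00875) and with the trends of length and GC content taken out (0.0220), against an adjusted p = 0.577 with an estimated correlation. The amino acid and endoplasmic reticulum stress list had 12 rising and 5 falling of 26, or 13 and 5 adjusted over the list alone (median 0.30, camera adjusted p = 0.329), with the chaperone HSPA5 at 1.03 and STC2 at 1.502. In the cholesterol, NF-kB, drug resistance and leukocyte lists the median was above 0 while the mean and the camera direction were below it. In the beta-catenin list the mean alone was below 0.

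Markers of other cell types gave no camera call in the main fit. Of the 12 fibroblast markers 5 stand in another list too, and the most abundant of them, COL1A2, was at 2289 CPM in the control libraries; it is named for that level, after its values were seen. Fibroblast markers had 6 rising and 2 falling of 9 tested, or 7 and 2 adjusted over the list alone (median 0.85, camera adjusted p = 0.207), with FAP at -1.28 and LUM at 2.08. Leukocyte markers had 2 falling and 1 rising of 7, or 2 and 3 adjusted over the list alone (median 0.10, camera adjusted p = 0.818), with CD3E, in the shifted stretch of chromosome 11, at -5.12 (-7.84 without DDX5 shRNA replicate 2) and CD14 at 1.37. The erythroid markers were too few for a set test, and SLC4A1 was at -0.74 (edgeR adjusted p = 0.0606; -1.05 and called, 0.0166, with length and GC trends taken out). Keratinocyte and cervical epithelial markers had 2 falling of 3 (median -1.21, camera adjusted p = 0.0653), KRT17 (-3.08) and TP63 (-1.21). That list was called without DDX5 shRNA replicate 1 (0.0354) or 2 (0.0370), without a low-count filter (0.0235) and with the trends of length and GC content taken out (0.0402), against an adjusted p = 0.577 with an estimated correlation.

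Processed pseudogenes, copies of spliced mRNAs in the genome, were lower. Of 1348 tested, 568 were lower and 27 higher, and 42.1% lower compares with 20.3% of all other genes (Fisher's exact test, adjusted p = 4.13e-67). Of 13923 protein-coding genes 3446 were higher and 2949 lower, so 24.8% were higher against 14.3% of the other genes (Fisher's exact test, adjusted p = 1.25e-66). Of 1860 antisense genes 306 were higher and 293 lower, and of 1801 lincRNA genes 319 were higher and 381 lower. Genes are not independent replicates, so these tests describe the calls. How reads shared between processed pseudogenes and the mRNAs they copy were counted is not given in the sources used here. The pseudogenes' own levels are uncertain to that extent. Processed pseudogenes took 0.45%, 0.256% and 0.312% of the counts of control replicates 1 to 3. In DDX5 shRNA replicates 1 to 3 they took 0.176%, 0.139% and 0.207%, beside lower shares of miscellaneous and small nucleolar RNA.

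Fold changes ran together over long stretches of several chromosomes. In windows of 50 neighbouring tested genes, 95 of 1927 medians lay beyond every one of 1000 shuffles of the gene order. With the trends of GC content, transcript length and expression level taken out, runs of at least 3 such windows formed 10 stretches. Genes were lower on chromosome 2 (24.0 to 27.9 Mb, median -0.33), 5 (10.4 to 40.8 Mb, median -0.68), 9 (2.90 to 19.4 Mb, median -0.64), 11 (109 to 131 Mb, median -0.53) and X (108 to 141 Mb, median -0.72). They were higher on chromosome 19 in 3 stretches (19.2 to 35.4, 34.2 to 39.4 and 55.8 to 58.5 Mb, medians 0.62, 0.67 and 0.54) and on chromosome 20 in 2 (35.2 to 46.0 Mb and 46.0 to 58.9 Mb, medians 0.60 and 0.59). The shift had the same direction in all 3 DDX5 shRNA libraries. On chromosome 9, protein-coding genes at a mean log2 CPM of at least 3 had a median of -0.32. In the first stretch of chromosome 20, such genes had medians of 0.50, 0.65 and 0.68 against the control mean. The 10 stretches hold 1070 tested genes (5.26%) and 648 changed genes (7.38%). Of the 68 nuclear OXPHOS genes 5 lie inside, and the median of the others was -0.57.

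**Figure D3:**
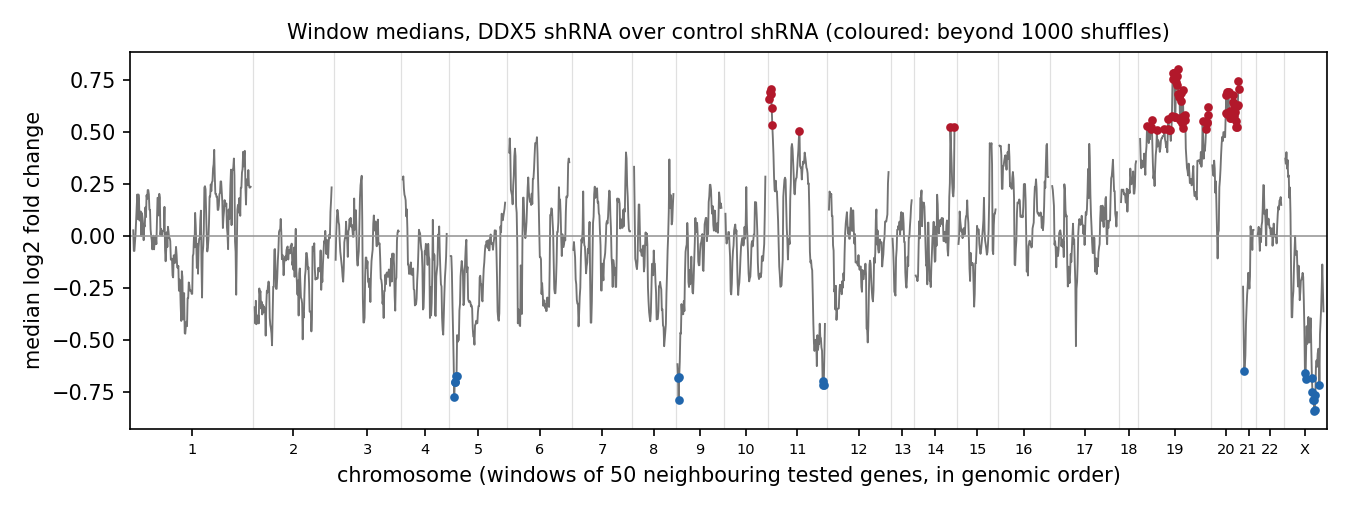
Median log2 fold change (DDX5 shRNA over control shRNA) in windows of 50 neighbouring tested genes along chromosomes 1 to 22 and X. Coloured points are the 95 windows beyond every one of 1000 shuffles of the gene order, 22 lower (blue) and 73 higher (red).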

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

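Of the tests in this part, both on admixed control cells were chosen after the result was seen.

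DDX5 shRNA replicate 1 held counts for 14378 genes too low to test, against at most 8761 in a control library, a signal in data that the comparison does not use. It also stood apart among tested genes, on the second principal component, at -64.9 against 22.7 and 29.2 in DDX5 shRNA replicates 2 and 3. Control cells mixed into that library would not bring genes absent from the controls, yet 4317 genes were counted there alone, against at most 449 in another library, which argues against that source for these genes. For the tested genes it cannot be told apart: DDX5 in replicate 1 exceeded replicates 2 and 3 by 0.733% of the gap to the control level (SE 2.08), and the middle range of 42 strongly lowered genes, picked for low values in replicates 2 and 3, was 2.10% to 6.83%. Background reads spread over all genes may account for part of it. The distance to replicates 2 and 3 was 1.70 to 1.76 times theirs in genes below a mean log2 CPM of 5. From 5 up it was 1.503 times (95% bootstrap interval 1.45 to 1.55, across a bound of 1.5 set beforehand), and from 7 up 1.31 times. The bootstrap resampled genes, so its interval does not measure the spread between libraries. Background reads thus stay open as a source, and no biological explanation was tested.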

How the results depend on the processing

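Of these settings, the removal of length and GC trends and the omission of shifted stretches were chosen after the data were seen. DDX5 stayed between -2.19 and -1.96 and DDX17 between 0.51 and 0.59 in the 17 alternatives with values for single genes, both called. The test against a fold of 1.5, the threshold of 0.01 and protein-coding genes alone gave counts of genes only. The count of changed genes was 5550 to 11510 when 1 library was left out (2764 to 5927 higher, 2786 to 5583 lower). It was lowest without control replicate 1, where 5491 of the 5550 were among the 8784, and highest without DDX5 shRNA replicate 1. Against a fold of 1.5 it was 2199 (978 higher, 1221 lower), and at 0.01 it was 5003 (2536 higher, 2467 lower), both stricter by construction. The other scalings, filters and tools gave 7570 to 9358, and protein-coding genes alone 6498. With length and GC trends out 9900 changed, 5431 higher and 4469 lower, 7271 of them among the 8784. The nuclear OXPHOS list was called in every alternative with a set test (adjusted p at most 0.0149) except with an estimated correlation, adjusted p = 0.577. That estimate, 0.462, takes up the spread shared by the list's genes. Of the 41 other lists 14 were called by camera, 0 with an estimated correlation, 31 by directional and 41 by mixed fry, which ask another question. The TCA cycle list passed by fry alone, directional (0.0276) and mixed (0.000625). Called class differences numbered 15, and 29 without a filter, where more genes are tested. With length and GC trends out, PRIMPOL (0.0022) and MTERF3 (0.083) turned from lower to higher, neither called; the cause was not tested. Of the other named genes, COX7C, UQCRH, SDHB, SDHA, MRPL33, TOMM7, SLC2A1, HADHB, HMGCS1, CCNB1, RPL39, LTV1, PRPF6, CREBBP, NOTCH2 and SNHG6 moved by over 1.5 times and kept their calls. With these trends out the medians of the NF-kB, import, biogenesis, coenzyme Q, glycolysis, cholesterol, beta-catenin and drug resistance lists turned to the other side of 0, with a call for NF-kB. With 1 library left out, those of the mitochondrial mRNA, leukocyte, drug resistance, splicing, helicase, glycolysis, cholesterol and NF-kB lists did so, uncalled. Without a filter the p53 (0.00474) and apoptosis (0.0341) lists were called too. With the replicate number as a block 8924 genes changed (4297 higher, 4627 lower), 8316 of them among the 8784. The block added the camera calls of complex III (0.0495) and NRF2 targets (0.0421), left out the calls of SDHA (0.0510), MT-CO2 (0.0825) and MGME1 (0.0558), and changed no other call of a list or named gene. Whether equal numbers mark paired libraries is not settled. Deviations of same-numbered libraries correlated at 0.053, 0.189 and 0.081, and those of differently numbered ones at -0.196 to 0.103. Control replicate 1 correlated better with DDX5 shRNA replicate 3 (0.103) than with DDX5 shRNA replicate 1. The seed site difference stayed between -0.03 and 0.05 without a call. Small changes can be missed: 35.7% of simulated 1.5-fold changes were recovered, with 200 changed genes among 19774 tested and 158 calls. With 8784 calls in the real data the adjusted threshold is less strict, so that share does not measure what was missed here. The simulation erred the other way too: 9.49% of its 158 calls were unchanged genes, above the adjusted p threshold of 0.05.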

Other observations

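Of the tests in this part, the one on the GC content and length trend along the chromosomes was chosen after the pattern was seen and its prediction written before its own result; the length and GC setting was also chosen after the data were seen.

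ABCC1, which encodes the drug efflux pump MRP1, is abundant in these cells and rose by 1.05 (SE 0.134, edgeR adjusted p = 0.000757), from 5346 ± 314 to 11098 ± 2035 CPM. It is named beyond the rule because of its level, chosen after its values were seen. At least 16-fold falls were called for 96 genes and 16-fold rises for 24 (94 and 24 with genes without a count in 1 group at their bound), and 55 of the 96 are protein-coding. In 73 of the 96 every DDX5 shRNA library was under 1 CPM.

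The fall of nuclear OXPHOS transcripts, median -0.56, was weighed against the trends of short and of GC-poor transcripts. Random lists matched on length and expression had a median of -0.17 (95% range -0.31 to -0.06), and lists matched on GC content 0.06 (-0.06 to 0.18); 0 of 10000 reached the list's median in either set. With both trends out of every library the list kept its call (camera adjusted p = 4.46e-05) at a median of -0.27. The trends as modelled may thus account for part of the size, and a remainder was left. The random lists do not carry the spread shared by the list's genes. With that correlation estimated (0.462), the camera adjusted p in the main fit was 0.577. Left-out libraries did not end the call (highest camera adjusted p 3.36e-05). Since cytosolic ribosomal proteins and histones fell too, a fall that is specific to mitochondria is not shown; a response to the loss of DDX5 remains a hypothesis, untested with 1 shRNA.

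The largest falls and the chromosome stretches may reflect that both cell populations differ genetically, beyond the shRNA. In the windows of neighbouring genes, 95 medians lay beyond every shuffle (22 lower, 73 higher), as a gain or loss of chromosome segments would give. With GC content, length and expression trends out, 73 medians did (36 lower, 37 higher), not all of them in the same windows. The longest run of such windows went from 24 to 14. That runs remained argues against those trends as the whole cause. The medians on chromosomes 19 and 20 run from 0.54 to 0.67, around the log2 of 1.5, 0.58, and those of the lowered stretches from -0.72 to -0.33, and these sizes were not tested against copy number steps. As a group, the 16-fold falls of protein-coding genes are not seed effects of the guide as printed: 7.27% (4 of 55, 95% exact interval 2.02% to 17.6%) carry its seed site. Among 13680 tested protein-coding genes with an annotated 3′ UTR the share was 8.60%. The other genes with 16-fold falls were not searched for sites. Of the 96, 11 lie in the stretches. Deletions cannot be told apart for them as a group: the nearest tested genes, members of the group included, had a median of -0.81 (-1.07 to -0.48). The 165 protein-coding neighbours outside the group had a median of -0.20 (-0.42 to -0.12), so deletions that reach such neighbours are not shown. Among protein-coding genes, 1 adjacent pair fell at least 16-fold together, against a median of 0 and at most 3 in 1000 shuffles. No DNA was analysed here, so regional regulation also stays open.

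Transcripts with a seed site of the guide were not lower: their median differed by 0.0071 from those without, above 66.0% of the 2248 comparable 7-mers, and for the opposite strand by 0.00017, above 53.8% of 2260. This holds for a guide that starts at the first printed base, and other starts were not tested. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 8784 changed genes, and the highest of the others gave 0 by edgeR (at most 772 at an unadjusted p under 0.05, against 10617) and 3 by DESeq2 (against 9358). For 16-fold changes in 1 direction it was again 1 of 10, with 96 genes against 0. The splits are too few for a share under 0.05. Every other split also mixed control and DDX5 shRNA libraries on each side. Their difference then adds to the spread within a side, so few calls were likely beforehand and give no measure of chance.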
